A study of Mus musculus with 10 samples.

How the data were processed

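RNA had been taken with Trizol from mouse embryonic fibroblasts grown in DMEM with 10% serum and hybridised to 10 Affymetrix arrays. The log2 values analysed here are those the authors deposited, 1 per probe set and array, made with GCRMA per the submitters' processing notes, which give no version. That they are on the log2 scale was read from the deposited values, which ran from 1.09 to 16.0 with array medians of 3.03 to 3.16. The chip definition and any filter are not given in the sources used here. The labels name 4-hydroxytamoxifen (OHT) at 1 µM or 5 µM for 4 days, and the source name says tamoxifen. The description calls all 10 samples conditional Dicer knockout, while the titles name 4 of them wild type (WT), and the titles were followed.

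Arrays were grouped by line and dose into 5 groups of 2. Of the probe sets, 64 controls were left out and 20681 with a highest group mean of at least 4 were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes on 5 group means, 5 residual degrees of freedom, Benjamini-Hochberg adjusted p under 0.05). Genes with a single symbol were represented by the probe set with the highest mean, which gave 10623 tested genes. The 8 comparisons were treated conditional knockout (CDKO) cells against the 3 control groups, as the design text of the series sets out, CDKO at 5 µM and at 1 µM against untreated, 5 µM against 1 µM, WT at 5 µM against untreated, the difference between the lines in the response to 5 µM, and CDKO against WT untreated and at 5 µM. Errors are SE of the model or SD between arrays, as stated. Spread was pooled over all groups although the CDKO replicates scattered more than the WT replicates, so that tests among CDKO groups use too small a spread and tests among WT groups too large a spread. A change from or to a mean under 4 is measured against background and is not a ratio of transcript amounts.

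The genes named are, by a rule fixed before the data were examined, those with the largest change among the genes past the threshold: up to 10 in each direction for the first 2 comparisons and for the difference between lines, up to 5 for the others, the 5 with the smallest p where none passed, up to 4 members of a list with the largest absolute change, and Dicer1. Symbols that are clone or model names were passed over. The groups, comparisons, lists and most alternatives were also fixed before the data were examined. The 26 gene lists covered microRNA machinery, let-7 targets, targets of other fibroblast microRNAs, p53 targets, mitosis, DNA replication, senescence and secretion, interferon-stimulated genes, cholesterol biosynthesis and uptake, the unfolded protein and integrated stress response, NRF2 and aryl hydrocarbon receptor targets, lysosome and autophagy, hypoxia and glycolysis, extracellular matrix, actin and myofibroblast genes, imprinted genes, Hox genes, sex-linked markers, and markers of fibroblasts, macrophages and leukocytes, endothelium, epithelium, skeletal muscle, neural and glial cells, adipocytes, and cartilage and bone. They were written from general knowledge and tested with camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated per list. The second form also uses the few residual degrees of freedom of the fit, so a call lost there need not reflect correlation between genes. For the cholesterol genes at 5 µM in CDKO cells, with a mitosis covariate, the estimated correlation was -0.0378. Their camera adjusted p still went from 6.37e-14 to 0.0256.

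The fit was tested on simulated data with independent arrays and the spread pooled over all 5 groups, which is smaller than that of the CDKO groups. Changes of 1, 2, 3 and 4 on the log2 scale were set in 50 probe sets each between untreated CDKO cells and 5 µM. The fit recovered 8%, 72%, 90% and 94% of them, with 7 unchanged probe sets among 139 called. The alternatives were no filter or a filter at 6, a trended robust prior, centring, quantile normalization, 1 probe set per gene, array weights, a replicate block, the compared groups alone, a minimum change of 1, other models of the first comparison, and each array left out in turn. A block for the class of the spike-in level, the first comparison without untreated WT cells, a crossed replicate block and list tests without each array were chosen after seeing the data. Replicate numbers were not treated as pairs, since replicate differences of untreated and 1 µM CDKO cells correlated at -0.453 and those of untreated and 5 µM cells at 0.431. A test of microRNA sites in 3' untranslated regions was not run, as no such sequences were given.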

Results

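Gene expression was measured in mouse embryonic fibroblasts, cells grown out of mouse embryos, on 10 arrays. A total of 6 arrays came from cells with a conditional knockout of Dicer (CDKO), the enzyme that cuts microRNA precursors, and 4 came from wild-type (WT) cells. The CDKO cells were untreated or had been given 1 µM or 5 µM of 4-hydroxytamoxifen (OHT) for 4 days. The WT cells were untreated or had been given 5 µM, and each of the 5 groups had 2 arrays. OHT is a ligand of the estrogen receptor that is commonly used to switch on a Cre recombinase fused to that receptor. The labels do not say whether the 2 arrays of a group came from separate cultures, so the p values given here may measure technical spread only. Between 41.8% and 43.2% of the probe sets had a log2 value of 4 or above in an array, and the small number of arrays limited the precision.

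The WT replicates lay close together and the CDKO replicates did not. The median SD between replicates was 0.10 in untreated WT and 0.07 in treated WT cells, against 0.31 in untreated CDKO, 0.34 in CDKO at 1 µM and 0.29 in CDKO at 5 µM (log2, n = 2 arrays each). In 4 of the 6 CDKO arrays the array with the highest correlation belonged to another group, for example CDKO untreated replicate 2 and CDKO 1 µM replicate 1 (r = 0.996 across probe sets, which are not independent). The hybridisation spike-in controls fell into a lower class in CDKO untreated replicate 2, both CDKO 1 µM arrays and CDKO 5 µM replicate 2, and into a higher class in the other arrays. The macrophage and leukocyte markers moved with that class among the CDKO arrays: their centred median was 0.04 and 0.67 in the CDKO arrays of the higher class and between -1.36 and -1.02 in those of the lower class. The median of the mitosis genes also parted the replicates, with 0.46 and -0.73 in untreated CDKO and -0.72 and 0.78 in CDKO at 1 µM. The 18S ribosomal RNA control was high in untreated WT (11.6 and 11.2) and in CDKO 1 µM replicate 2 (10.2), against 5.21 to 8.44 elsewhere. The 3' to 5' difference of the Gapdh control was 0.89, 0.67 and 1.58 in those 3 arrays.

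**Figure D1:**
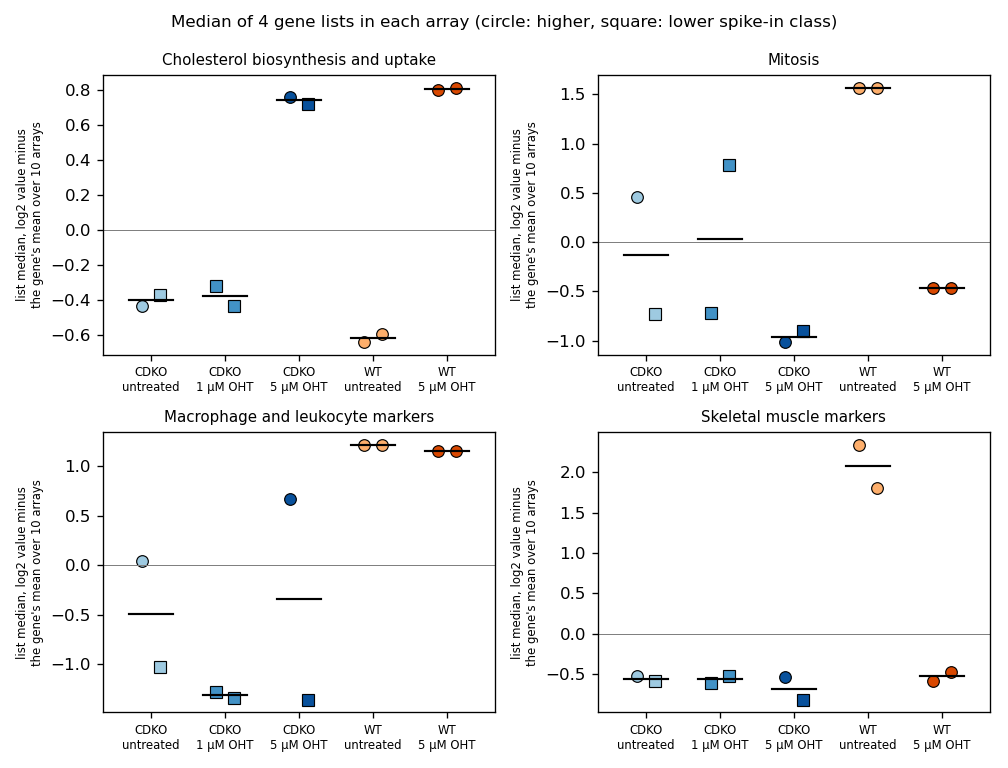
Median log2 value of the measured members of 4 gene lists in each array, after subtracting each gene's mean over the 10 arrays; points are arrays, bars are means of the 2 arrays of a group, and the marker gives the spike-in class. The cholesterol list stood at 0.72 to 0.81 in all 4 arrays at 5 µM and at -0.32 or lower in the others, while the muscle list was above 0 in untreated WT alone (2.33 and 1.81).

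Dicer1 was measured by 2 probe sets. Whether either lies in the deleted part of the gene is not given in the sources used here, so the values show neither that the deletion took place nor that it did not. The probe set with the lower signal stood at 6.13 ± 0.28 in untreated CDKO, 6.33 ± 0.32 at 1 µM and 5.69 ± 0.29 at 5 µM (log2, SD, n = 2 each). In WT cells it stood at 7.24 ± 0.11 untreated and 5.92 ± 0.03 treated. It fell by 1.32 ± 0.26 (SE; adjusted p = 0.0266) with OHT in WT cells and was lower in untreated CDKO than in untreated WT cells by -1.11 ± 0.26 (adjusted p = 0.0481). The change in CDKO cells at 5 µM was -0.44 ± 0.26 and did not pass the test (adjusted p = 0.746). The other probe set passed the test in none of these 3 comparisons, with -0.73 ± 0.83 in CDKO cells at 5 µM (adjusted p = 0.929) and -1.62 ± 0.83 in WT cells (adjusted p = 0.233). In CDKO at 1 µM its 2 arrays read 5.40 and 8.30. Both probe sets were highest in the arrays with a raised ribosomal RNA control, untreated WT and CDKO 1 µM replicate 2. The other probe set read 8.97, 9.10 and 8.30 there and at most 7.64 elsewhere. The probe set with the lower signal read 7.31, 7.16 and 6.55 there and at most 6.33 elsewhere. In the contrasts with untreated WT cells, drug or line therefore cannot be told apart from the difference in that control.

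**Figure D2:**
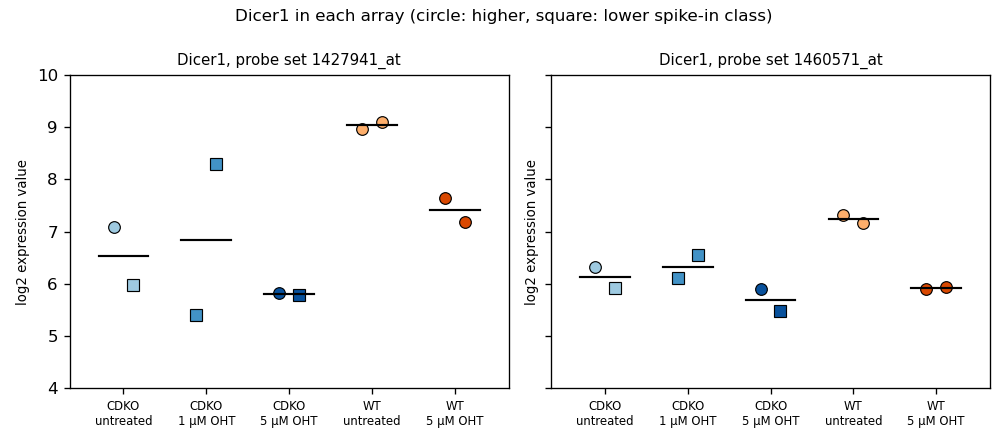
Log2 expression value of the 2 Dicer1 probe sets in each array, with bars at the mean of the 2 arrays of a group and the marker giving the spike-in class. The highest group means are those of untreated WT cells (9.03 and 7.24).

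The design text of the series sets the 4 arrays of treated CDKO cells against the 6 arrays of the 3 control groups. Adh7, an alcohol dehydrogenase that acts on retinol, was higher by 2.14 ± 0.16 in that comparison (log2, SE, n = 4 and 6; adjusted p = 0.0019). Its mean went from 3.24 ± 0.41 (SD) in untreated CDKO to 4.64 ± 0.21 at 1 µM and 5.45 ± 0.02 at 5 µM. Most other named genes parted the lines rather than the treatments. Esr1, the gene of estrogen receptor alpha, was higher by 3.91 ± 0.46 (on 1 of 3 probe sets, adjusted p = 0.0080) and Cdkn2a, which encodes the cell cycle inhibitors p16 and p19, by 3.05 ± 0.31 (adjusted p = 0.0051). Both were already high in untreated CDKO cells (8.71 ± 0.52, SD, for Cdkn2a) and low in untreated WT cells (3.62 ± 0.24). The neuropeptide gene Vip (-4.29 ± 0.17, adjusted p = 1.41e-04), Mid1 (-2.76 ± 0.21) and Zfp979 (-2.58 ± 0.22) had group means under 4 in every CDKO group. Zfp991, Sema7a, Max, Ttc9, Zc3h7b, Itgb3 and Serpina3n were higher by 2.05 to 3.12, and Ccl6, Hddc3, Mef2c, Sftpc, Taf15, Ccl12 and Lmo1 differed by -2.51 to -2.04. With a line term the direction turned for Zfp991 (-0.037), Serpina3n (-0.011), Ccl6 (0.38), Hddc3 (0.094) and Sftpc (0.13), and for Sftpc also without untreated WT cells (0.13). Sftpc, a lung surfactant gene, was above background in untreated WT cells alone (9.25 ± 0.11).

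Among the lists, 2 of 15 measured NRF2 and aryl hydrocarbon receptor targets were higher in the same comparison (4 when adjusted over the list alone), with Nqo1, a quinone reductase, at 1.77 ± 0.19 and Srxn1, which repairs peroxiredoxins, at 1.41 ± 0.26. Nqo1 was already higher in untreated CDKO than in untreated WT cells by 1.95 ± 0.30. The list median was 0.32 (camera, adjusted p = 6.69e-05, adjusted p = 0.0678 with an estimated correlation). Of 24 p53 targets 2 were higher, Pmaip1 and Tnfrsf10b (1.23 ± 0.23) (4 when adjusted over the list alone, adjusted p = 0.408 with an estimated correlation). Pmaip1 was already higher in untreated CDKO than in untreated WT cells by 2.75 ± 0.50. Of 21 senescence and secretory genes Cdkn2a and Ereg (0.83 ± 0.14) were higher and Cxcl5 (-1.77 ± 0.28), Mmp3 and Hgf lower (4 and 4 when adjusted over the list alone). Within the CDKO line Mmp3 rose at 5 µM (4.73 to 7.50), to above untreated WT cells (6.75) and below treated WT cells (9.96). At 1 µM its change from untreated CDKO cells was -1.02 ± 0.24, which did not pass over all genes. The list was not shifted (median 0.42, camera adjusted p = 0.460). The macrophage and leukocyte markers had a median of -1.39, with C1qa (-2.04 ± 0.38) and C1qc (-1.55 ± 0.32), 2 of 15, lower (13 when adjusted over the list alone). The shift had a camera adjusted p = 2.49e-10 and adjusted p = 0.340 with an estimated correlation. These markers moved with the spike-in class (-1.28, -1.34 and -1.36 in the 3 treated CDKO arrays of the lower class, 0.67 in the other), and the median was -0.43 with the class as a block (camera adjusted p = 9.02e-04). Of 11 muscle markers Actc1, Myl1, Myh3, Tnni1 and Mylpf were lower (6 when adjusted over the list alone, median -0.78, adjusted p = 0.0678 with an estimated correlation). Of 5 epithelial markers Krt8 and Cdh1 were lower by either adjustment (median -0.33, adjusted p = 0.0945 with an estimated correlation), and of 6 adipocyte markers Pparg and Adipoq (5 when adjusted over the list alone, median -0.88, adjusted p = 0.0678 with an estimated correlation). The muscle and epithelial genes named here and Adipoq stood higher in untreated WT cells, which had a raised 18S control, than in the 4 other groups (6.79 against 3.16 to 3.52 for Actc1, 8.81 against 2.93 to 3.06 for Krt8). They part these cells from the rest and not treated CDKO cells from the controls, while Pparg was high in both WT groups (7.39 and 7.25). Ereg, Hgf, C1qc, Mylpf and Adipoq were named after their values were seen.

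By limma, 843 of 20681 probe sets passed in the comparison of treated CDKO cells with the control groups, 247 higher and 596 lower. As 2 groups of 4 and 6 arrays 1 probe set passed, and with the line as a term 0 did (427 at an unadjusted p under 0.05). A total of 15 passed without the untreated WT group, 259 with the spike-in class as a block, 104 with array weights, 538 with a replicate block and 184 counting 1 probe set per gene. The count was 535 without CDKO untreated replicate 1, 1455 without replicate 2, 547 without CDKO 5 µM replicate 2, 304 and 221 without WT untreated replicates 1 and 2, and 142 and 194 without WT 5 µM replicates 1 and 2. Of the 20 named genes 9 passed throughout when each array was left out and 0 throughout the other alternatives.

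In CDKO cells, 5 µM OHT and no treatment were compared within the line named conditional knockout. Akr1c18, which inactivates progesterone, rose by 4.49 ± 0.44 (log2, SE, n = 2 each; adjusted p = 0.0335). The antioxidant genes Nqo1 and Slc7a11, a cystine transporter, rose by 2.55 ± 0.30 (adjusted p = 0.0378) and 3.07 ± 0.23 (adjusted p = 0.0114). The serine protease inhibitors Serpinb9g and Serpinb1b rose by 4.30 ± 0.52 and 4.23 ± 0.47 and the matrix protease gene Mmp3 by 2.77 ± 0.24. Rises were also seen for the adhesion molecule Nrcam by 3.52 ± 0.32, the transporters Slco4a1 and Abcc4 by 2.71 ± 0.32 and 2.66 ± 0.25, and the acetylcholine receptor subunit Chrna7 by 2.56 ± 0.32. Both arrays at 5 µM lay above both untreated arrays for each of these 10 genes, which were chosen by their difference on these same arrays. The untreated means of Akr1c18 (2.15), Serpinb9g (2.66), Serpinb1b (2.51), Nrcam (3.37), Slc7a11 (2.75) and Chrna7 (2.62) were under 4, so the sizes of these changes were measured from near background. Within the higher and the lower spike-in class the differences were 5.22 and 3.77 for Akr1c18, 2.83 and 2.27 for Nqo1, 4.06 and 2.99 for Nrcam, and 2.96 and 2.35 for Abcc4 (1 array against 1 each). No gene chosen by the naming rule fell; Tcf12 (-1.86 ± 0.19), Fbxl7 (-2.85 ± 0.33) and Trps1 (-2.13 ± 0.25), named after their values were seen, each fell on 1 probe set.

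**Figure D3:**
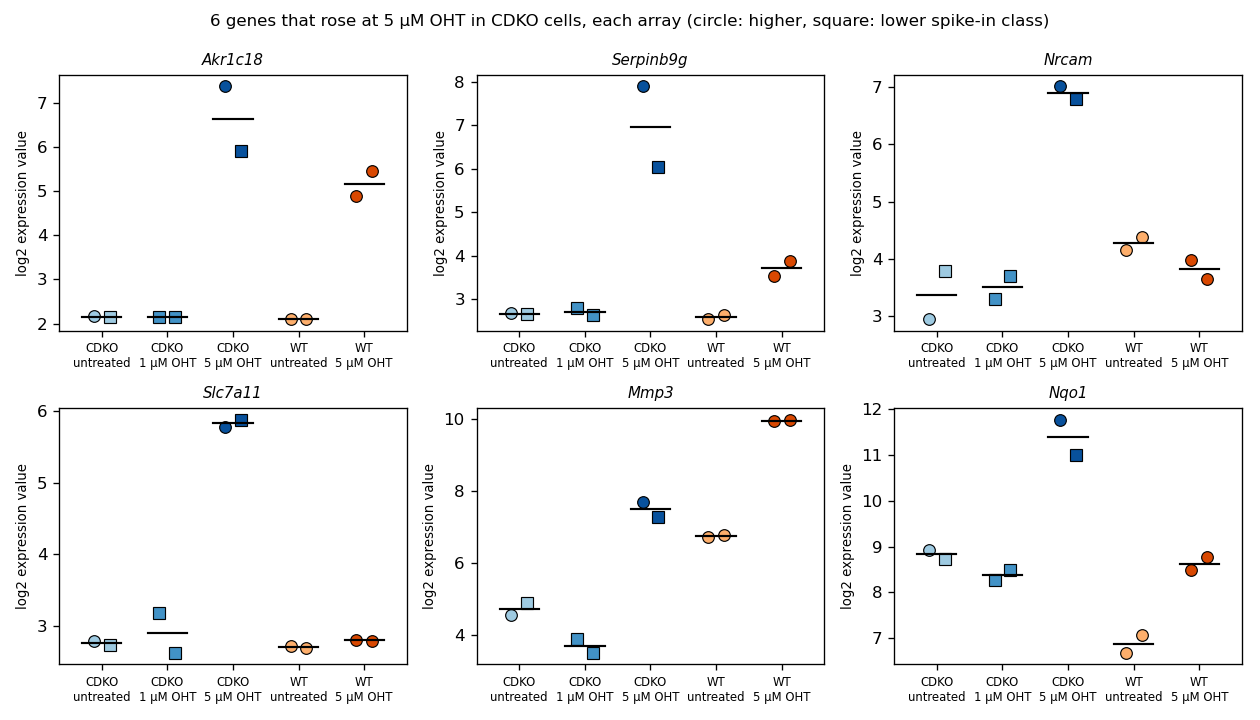
Log2 expression value of 6 genes that rose at 5 µM OHT in CDKO cells, in each array, with bars at the mean of the 2 arrays of a group and the marker giving the spike-in class. Slc7a11 and Nrcam stood above the other groups in CDKO at 5 µM alone (5.83 and 6.89), whereas Akr1c18 and Mmp3 were also higher in WT cells at 5 µM than in untreated WT cells.

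All 20 measured genes of cholesterol biosynthesis and uptake had a positive change at 5 µM in CDKO cells, with a median of 1.15 (camera, adjusted p = 1.39e-22, adjusted p = 0.0115 with an estimated correlation). Idi1, an isomerase of the mevalonate pathway, rose by 1.71 ± 0.21 (adjusted p = 0.0432) and was the only 1 of the 20 that passed over all genes. A total of 15 passed when adjusted over the list alone, among them Tm7sf2 (1.87 ± 0.33), Nsdhl (1.84 ± 0.45) and Hsd17b7 (1.48 ± 0.23). The list median was 1.21 within the higher and 1.17 within the lower spike-in class, and 1.15 with the class as a block (adjusted p = 6.57e-19). Of 15 measured NRF2 and aryl hydrocarbon receptor targets Nqo1 alone rose over all genes and 6 when adjusted over the list alone, including Srxn1 (2.48 ± 0.41), Gclm (1.83 ± 0.42) and Gclc (1.82 ± 0.37). Their median was 0.87 (adjusted p = 1.05e-07, adjusted p = 0.0234 with an estimated correlation), 0.76 and 0.99 within the classes, and 0.87 with the block (adjusted p = 1.04e-06).

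Other lists shifted by camera at 5 µM in CDKO cells lost the call with an estimated correlation. Hypoxia and glycolysis genes had a median of 0.62 (0 of 20 rose, 5 when adjusted over the list alone, among them Slc2a1 at 1.26 ± 0.21, adjusted p = 0.173 with an estimated correlation; 0.76 and 0.42 within the classes). Lysosome and autophagy genes had a median of 0.28, with Gpnmb up by 2.03 ± 0.22 (1 of 23 rose, 2 when adjusted over the list alone, adjusted p = 0.116 with an estimated correlation). Senescence and secretory genes had a median of 0.71 (1 of 21 rose, Mmp3, and 3 when adjusted over the list alone, adjusted p = 0.450 with an estimated correlation). Mitosis genes had a median of -0.89 with 0 of 25 called by either adjustment (camera adjusted p = 4.41e-08, adjusted p = 0.450 with an estimated correlation). The difference was -1.48 in the higher class and -0.29 in the lower. Extracellular matrix genes had a median of -0.70 with 0 of 30 called by either adjustment (adjusted p = 0.450 with an estimated correlation), -1.43 in the higher class and 6.08e-04 in the lower. The sign of that median turned without CDKO 5 µM replicate 1. Interferon-stimulated genes had a median of -0.59 (0 of 20 fell, 1 when adjusted over the list alone, Oasl2 at -1.89 ± 0.36, adjusted p = 0.450 with an estimated correlation), -0.79 and -0.37 within the classes.

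By limma, 30 probe sets passed at 5 µM against untreated CDKO cells, 24 higher and 6 lower, and 1839 had an unadjusted p under 0.05. With the 4 arrays of these groups alone 0 passed (993 at an unadjusted p under 0.05), with array weights 2, with a replicate block 3 and without the filter 46; 37 passed with the spike-in class as a block. The count was 0 without CDKO untreated replicate 1 (1348 at an unadjusted p under 0.05), 121 without CDKO untreated replicate 2, 7 without CDKO 5 µM replicate 1, 88 without CDKO 5 µM replicate 2 and 2 without any 1 of the 4 WT arrays. All 10 named genes kept their sign in every alternative. Leaving out an array could not have turned it, as both 5 µM arrays lay above both untreated arrays, so the kept sign adds no support. By limma 0 of them passed throughout when each array was left out and 0 throughout the other alternatives.

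In WT cells, 5 µM OHT was compared with no treatment in 2 groups that also differed in the 18S control. The cholesterol genes were again higher as a group: 14 of 20 rose (18 when adjusted over the list alone), with a median of 1.33 (camera, adjusted p = 5.54e-14, adjusted p = 0.0352 with an estimated correlation). With an estimated correlation this call was lost after centring (adjusted p = 0.0579) and after quantile normalization (adjusted p = 0.0716). The list median was 1.33 and 1.40 there, with SD between genes of 0.57 and 0.56 (0.57 before), and the estimated correlation was 0.0666 and 0.0764 instead of 0.0431. Nsdhl rose by 2.36 ± 0.45, Tm7sf2 by 2.34 ± 0.33 and Fdps by 2.30 ± 0.48 (log2, SE, n = 2 each). Abca1, which exports cholesterol, fell by 6.16 ± 0.82 (adjusted p = 0.0093). The chemokine gene Ccl8 rose by 6.07 ± 1.07 (adjusted p = 0.0197), the interferon-induced Usp18 by 5.52 ± 0.96, Crct1 by 5.75 ± 0.94, the matrix protease gene Mmp10 by 4.60 ± 1.11 and the mast cell protease gene Mcpt8 by 4.07 ± 0.59. Sftpc (-7.04 ± 0.23, adjusted p = 2.43e-05), the keratin gene Krt8 (-5.84 ± 0.21), the bone sialoprotein gene Ibsp (-5.79 ± 0.19) and Sfrp2 (-4.48 ± 0.59) fell from group means above 7 to under 3.

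**Figure D4:**
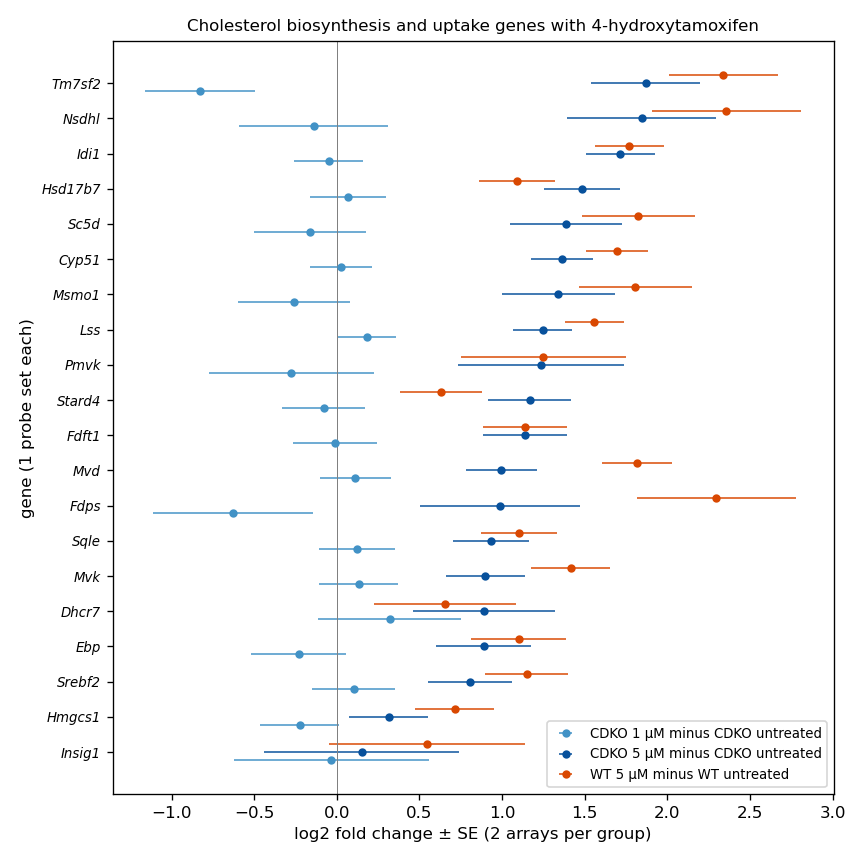
Log2 fold change with its SE (2 arrays per group) of the 20 measured genes of cholesterol biosynthesis and uptake, for CDKO cells at 1 µM and at 5 µM against untreated CDKO cells and for WT cells at 5 µM against untreated WT cells. All 20 points are above 0 at 5 µM in both lines (medians 1.15 and 1.33), and the median at 1 µM is -0.04.

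Mitosis genes were lower in treated than in untreated WT cells: 14 of 25 fell (23 when adjusted over the list alone), with Cenpf at -4.39 ± 0.99 and Mki67, a marker of dividing cells, at -3.61 ± 0.82. The median was -1.95 (camera, adjusted p = 2.35e-10, adjusted p = 0.298 with an estimated correlation). Of 27 DNA replication genes 7 fell (19 when adjusted over the list alone), with Pola1 at -2.47 ± 0.56 (median -1.35, adjusted p = 0.298 with an estimated correlation). Interferon-stimulated genes were higher: 6 of 20 rose (10 when adjusted over the list alone), with Xaf1 at 2.84 ± 0.63 (median 1.16, adjusted p = 0.243 with an estimated correlation). Of 21 senescence and secretory genes 5 rose (9 rose and 1 fell when adjusted over the list alone, median 0.63, adjusted p = 0.298 with an estimated correlation), namely Ccl8, Mmp10, Mmp3 (3.21 ± 0.24), Cdkn2a and Ccl7. Of 20 hypoxia and glycolysis genes Bnip3 (2.78 ± 0.35), Pdk1, Tpi1, Pgam1 and Ero1a rose (11 when adjusted over the list alone, median 0.86, adjusted p = 0.169 with an estimated correlation). Of 23 lysosome and autophagy genes Gpnmb (3.24 ± 0.22), Gla and Ctsz rose (4 when adjusted over the list alone, median 0.65, adjusted p = 0.156 with an estimated correlation). Of 24 p53 targets 2 rose, Pmaip1 by 2.07 ± 0.50 and Ddit4 by 0.83 ± 0.19 (3 when adjusted over the list alone, adjusted p = 0.307 with an estimated correlation). Ddit4, Tpi1, Pgam1, Ero1a and Ccl7 were named after their values were seen.

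Markers of other cell types also parted treated from untreated WT cells. Of 11 muscle markers 7 fell and 1 rose (8 and 1 when adjusted over the list alone), with Myl1 at -4.29 ± 0.27 and Myh3 at -3.34 ± 0.21 (median -2.38, camera adjusted p = 7.06e-07, adjusted p = 0.0942 with an estimated correlation). Of 5 measured epithelial markers Krt8 and Cdh1 (-3.37 ± 0.21) fell, the same number as when adjusted over the list alone (median -1.60, adjusted p = 0.156 with an estimated correlation). These groups moved together with the 18S control, which was 11.6 and 11.2 in the untreated and 6.16 and 5.98 in the treated WT arrays. The same holds for the mitosis genes.

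By limma, 1909 probe sets passed in WT cells, 725 higher and 1184 lower. The count was 11308 with the 4 WT arrays alone and 12458 with array weights. It was 2988 with the spike-in class as a block, 1190 with a replicate block and 937 counting 1 probe set per gene. Without WT untreated replicates 1 and 2 it was 225 and 119, without WT 5 µM replicates 1 and 2 it was 109 and 64, and without either CDKO 1 µM array it was 4503. Of the 10 named genes 3 passed throughout when each array was left out and 6 throughout the other alternatives.

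The responses of the lines to 5 µM were compared through the difference between them, CDKO minus WT. Nrcam (3.98 ± 0.45, SE; adjusted p = 0.0196), Abcc4 (3.19 ± 0.36; adjusted p = 0.0192) and Slc7a11 (2.98 ± 0.32; adjusted p = 0.0151) responded more in CDKO cells. In WT cells their changes were -0.45 ± 0.32, -0.54 ± 0.25 and 0.09 ± 0.23. Of the 15 genes that passed at 5 µM in CDKO cells, these 3 differed between the lines by that test, and 7 also rose in WT cells. Independent calls would give 0.518 such genes, but both tests share 1 pooled spread per probe set, so chance may give more. Those 7 were Akr1c18 (3.08 ± 0.44 in WT), Mmp3 (3.21 ± 0.24), Gpnmb (3.24 ± 0.22), Chrna7 (1.95 ± 0.32), Idi1 (1.77 ± 0.21), Nqo1 (1.75 ± 0.30) and Selp (1.15 ± 0.21). Across 10623 genes, which are not independent, the changes in the lines correlated with r = 0.482 and rho = 0.414. Angptl7 (-3.10 ± 0.33), Hal (-2.98 ± 0.26) and Gjb2 (-2.31 ± 0.30) rose in WT cells at 5 µM and stayed near their untreated level in CDKO cells. The positive differences of Sftpc (7.03 ± 0.33), Ibsp (5.79 ± 0.26), Krt8 (5.71 ± 0.30), Myl1 (4.48 ± 0.39), Gprin3 (4.32 ± 0.25), Saa3 (3.72 ± 0.26), Cdh1 (3.31 ± 0.29) and Myh3 (3.16 ± 0.30) went with a fall in WT cells from a level that no CDKO array reached.

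Of 20 interferon-stimulated genes all had a lower response in CDKO than in WT cells, with a median difference of -1.80 (camera adjusted p = 3.37e-15, adjusted p = 0.166 with an estimated correlation). By limma 0 passed over all genes and 11 when adjusted over the list alone, among them Usp18 at -6.76 ± 1.35 and Xaf1 at -4.24 ± 0.89. Untreated CDKO cells already stood above untreated WT cells, at 7.25 against 2.93 for Usp18 and 8.97 against 5.83 for Ifit3. Mitosis genes differed by 1.26 and DNA replication genes by 1.06 (0 of 25 and 0 of 27 passed by either adjustment, adjusted p = 0.505 and 0.423 with an estimated correlation), from a higher level in untreated WT than in untreated CDKO cells. The cholesterol list differed by -0.34 (0 of 20 by either adjustment, camera adjusted p = 0.0299, adjusted p = 0.318 with an estimated correlation). The NRF2 and aryl hydrocarbon receptor targets differed by 0.61, which did not pass (0 of 15 over all genes, 1 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.0693).

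By limma, 72 probe sets passed for the difference between the lines, 59 higher and 13 lower. The count was 194 without the filter, 32 with a filter at 6, 39 counting 1 probe set per gene, 35 with a replicate block and 212 with the 8 arrays compared. It was 36 without CDKO untreated replicate 2, 212 without either CDKO 1 µM array, 35 without CDKO 5 µM replicate 1, 17 without WT untreated replicate 2, and 11 and 9 without WT 5 µM replicates 1 and 2. Sftpc, Ibsp, Krt8 and Gprin3 passed in every alternative, and 10 of the 16 named genes passed in all of those that kept all arrays.

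At 1 µM, no gene passed against untreated CDKO cells. The genes with the smallest p were Mars2 (-1.72 ± 0.25), Bcl11b (1.21 ± 0.19), Lrp2 (1.56 ± 0.27), Adh7 (1.40 ± 0.25) and Oasl2 (-2.04 ± 0.36; log2, SE, n = 2 each), all with an adjusted p of 0.887. The cholesterol genes had a median of -0.04 (8 of 20 positive, 0 called by either adjustment, camera adjusted p = 0.746). The NRF2 and aryl hydrocarbon receptor targets had a median of -0.09 (0 of 15 by either adjustment, camera adjusted p = 0.257). Interferon-stimulated genes had a median of -0.74 (0 of 20 fell, 1 when adjusted over the list alone, camera adjusted p = 5.91e-08, adjusted p = 0.830 with an estimated correlation). Macrophage and leukocyte markers had a median of -0.88 (0 of 15 by either adjustment, adjusted p = 0.830 with an estimated correlation), with both 1 µM arrays in the lower spike-in class. With the class as a block these 2 medians were -0.52 and -0.18 (camera adjusted p = 8.32e-07 and 0.0750). By limma, 0 probe sets passed and 710 had an unadjusted p under 0.05; 467 passed without CDKO 1 µM replicate 1 and 6 without CDKO untreated replicate 2. In simulated data a change of 2 on the log2 scale was called for 72% of the changed probe sets and a change of 1 for 8%. The simulation was of 5 µM against untreated CDKO cells, with the same number of arrays, taken as independent. Its spread was pooled over all 5 groups, while the CDKO groups scattered more (median SD of 0.34 at 1 µM against 0.10 and 0.07 in WT cells). These shares may therefore be too high for CDKO cells.

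Between the doses in CDKO cells, Mmp3 was higher at 5 µM than at 1 µM by 3.79 ± 0.24 (log2, SE, n = 2 each; adjusted p = 0.0041), Akr1c18 by 4.50 ± 0.44 (adjusted p = 0.0220). Rragd, a GTPase that signals nutrient state, was higher by 4.66 ± 0.58, Serpinb1b by 4.29 ± 0.47 and Serpinb9g by 4.25 ± 0.52. The cholesterol genes were higher by a median of 1.20 (2 of 20 passed, Tm7sf2 at 2.70 ± 0.33 and Idi1 at 1.76 ± 0.21, and 17 when adjusted over the list alone, camera adjusted p = 2.89e-18, adjusted p = 0.0189 with an estimated correlation). The NRF2 and aryl hydrocarbon receptor targets were higher by 0.87 (1 of 15 passed, Nqo1, and 6 when adjusted over the list alone, adjusted p = 0.0240 with an estimated correlation). With the spike-in class as a block both lists passed (camera adjusted p = 4.38e-20 and 4.11e-08), the second with a median of 0.81. Tcf12, named after its value was seen, was lower on 1 probe set by -1.78 ± 0.19. By limma, 35 probe sets passed, 33 higher and 2 lower. By limma 0 passed with the 4 arrays of these groups alone (996 at an unadjusted p under 0.05), 2 with array weights, 3 with a replicate block, 16 after quantile normalization and 21 counting 1 probe set per gene. The count was 1901 and 7 without CDKO 1 µM replicates 1 and 2, 8 and 293 without CDKO 5 µM replicates 1 and 2, and 3 without any 1 WT array. Only 1 of the 5 named genes passed throughout when each array was left out and 0 throughout the other alternatives.

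Untreated CDKO and untreated WT cells differ in line and carry no drug. Esr1 was higher in CDKO cells by 5.39 ± 0.71 on 1 of 3 probe sets (log2, SE, n = 2 each, adjusted p = 0.0077), Cdkn2a by 5.09 ± 0.48 (adjusted p = 0.0025). The other Esr1 probe sets had group means under 4 in both lines. Zfp991 was higher by 4.93 ± 0.52, Usp18 by 4.31 ± 0.96 and Rraga, a GTPase that signals amino acid supply, by 4.27 ± 0.51. Sftpc (-7.06 ± 0.23, adjusted p = 2.14e-05), Ibsp (-5.84 ± 0.19), Krt8 (-5.76 ± 0.21), Vip (-4.87 ± 0.27) and Mid1 (-4.54 ± 0.32) were lower. Of 11 muscle markers 7 were lower (8 lower and 1 higher when adjusted over the list alone, median -2.53, adjusted p = 0.0491 with an estimated correlation), with Myl1 at -4.31 ± 0.27 and Actc1 at -3.28 ± 0.21. Of 6 adipocyte markers Cebpa (-3.69 ± 0.63), Car3, Adipoq (-1.97 ± 0.17) and Fabp4 were lower (6 when adjusted over the list alone, median -2.68, adjusted p = 0.0491 with an estimated correlation). Of 25 mitosis genes Kif23, Plk1, Nek2, Ccna2 and Ube2c were lower (17 when adjusted over the list alone, median -1.65, adjusted p = 0.360 with an estimated correlation). Of 20 interferon-stimulated genes Usp18, Ifit3 (3.14 ± 0.57), Bst2 and Oasl2 were higher (8 when adjusted over the list alone, median 0.99, adjusted p = 0.214 with an estimated correlation). Of 15 NRF2 and aryl hydrocarbon receptor targets Nqo1 (1.95 ± 0.30) and Aox1 (1.43 ± 0.27) were higher (3 when adjusted over the list alone, median 0.14, camera adjusted p = 0.0536). Of 24 p53 targets Pmaip1 (2.75 ± 0.50), Fas (1.40 ± 0.26), Trp53inp1, Cdkn1a and Ddit4 were higher (7 when adjusted over the list alone, median 0.74, adjusted p = 0.214 with an estimated correlation). Fabp4, Plk1, Nek2, Ccna2, Ube2c, Bst2, Oasl2, Cdkn1a and Ddit4 were named after their values were seen. The 18S control was 6.87 and 8.44 in the untreated CDKO arrays against 11.6 and 11.2 in the untreated WT arrays. By limma, 1360 probe sets passed, 475 higher and 885 lower. A total of 2206 passed with the spike-in class as a block, 489 with the 4 arrays alone and 422 counting 1 probe set per gene. The count was 457 without CDKO untreated replicate 2, 323 and 243 without WT untreated replicates 1 and 2, 594 without either WT 5 µM array and 3214 without either CDKO 1 µM array. A total of 6 of the 10 named genes passed in every alternative.

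With 5 µM OHT in both lines, Esr1 (5.85 ± 0.71, SE, on 1 of 3 probe sets, adjusted p = 0.0124), Zfp991 (4.78 ± 0.52), Itgb3 (4.23 ± 0.73), Max (4.14 ± 0.77) and Serpinb1b (3.74 ± 0.47) were higher in CDKO than in WT cells (n = 2 each). Vip (-7.37 ± 0.27, adjusted p = 6.58e-05), Zfp979 (-4.44 ± 0.33), Ccl6 (-4.41 ± 0.56), Hddc3 (-3.65 ± 0.51) and Mid1 (-3.53 ± 0.32) were lower. The NRF2 and aryl hydrocarbon receptor targets had a median of 0.79 (1 of 15 higher, Nqo1 at 2.76 ± 0.30, and 6 when adjusted over the list alone, camera adjusted p = 1.18e-05, adjusted p = 0.0823 with an estimated correlation), and Nqo1 was already higher by 1.95 in untreated CDKO cells. The median was 0.89 with the spike-in class as a block (camera adjusted p = 5.23e-04). The cholesterol genes had a median of -0.17 (0 of 20 by either adjustment, camera adjusted p = 0.296). Macrophage and leukocyte markers had a median of -1.49 (0 of 15 by either adjustment, camera adjusted p = 1.18e-05, adjusted p = 0.746 with an estimated correlation), and -0.71 with the class as a block (camera adjusted p = 0.0207). By limma, 372 probe sets passed, 195 higher and 177 lower. A total of 944 passed with the class as a block, 197 with a replicate block, 156 counting 1 probe set per gene and 2 with the 4 arrays alone. The count was 594 without either CDKO 1 µM array, 170 without CDKO 5 µM replicate 1, 124 without either WT untreated array, and 29 and 30 without WT 5 µM replicates 1 and 2. Among the 10 named genes 2 passed throughout when each array was left out and 0 throughout the other alternatives.

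Target genes of microRNAs, which Dicer makes, were examined in each comparison. At 5 µM against untreated CDKO cells, 12 measured let-7 targets had a median of 0.13 (camera adjusted p = 0.289), with Myc at 0.84 ± 0.46 and Hmga2 at 0.83 ± 0.31 (log2, SE, n = 2 each). The 25 targets of other fibroblast microRNAs had a median of -0.02 (adjusted p = 0.896), with Vegfa at 1.15 ± 0.47 and Dnmt3a at -1.11 ± 0.52. By limma 0 passed in either list by either adjustment. In treated CDKO cells against the control groups the medians were 0.24 and -0.01 (camera adjusted p = 0.191 and 0.735), with 0 let-7 targets called and Mybl2 (-0.90 ± 0.14) lower among the others, 1 by either adjustment. Mybl2 was above background in untreated WT cells alone (5.23). In WT cells at 5 µM the medians were -0.16 and 0.03, and 1 let-7 target fell, Tgfbr1 (-1.35 ± 0.26), with Mybl2 (-2.92 ± 0.21), Dnmt3a (-2.64 ± 0.52), Bcl2 (-2.61 ± 0.52) and Bcl2l11 (-2.42 ± 0.53) of the others (1 let-7 target higher and 3 lower, and 5 of the others lower, when adjusted over the list alone). Between the untreated lines Igf1r (-1.68 ± 0.35), Igf2bp3 (-1.19 ± 0.24), Mybl2 (-2.90 ± 0.21) and Zeb2 (-2.30 ± 0.49) were lower in CDKO cells (1 let-7 target higher and 3 lower, and 3 of the others lower, when adjusted over the list alone). In the difference between the lines Mybl2 alone passed (2.85 ± 0.30). Igf1r (-1.38) and Igf2bp3 (-0.93) were among the let-7 targets that fell in WT cells at 5 µM when adjusted over the list alone. Untreated WT cells, which had a raised ribosomal RNA control, enter all 3 of these comparisons. Drug or line therefore cannot be told apart there from the difference in that control. Neither list passed by camera in any of the 8 comparisons, and in the remaining 3 comparisons 0 targets passed by limma by either adjustment. The 19 measured genes of the microRNA machinery had a median of -0.15 at 5 µM in CDKO cells (0 called by either adjustment, camera adjusted p = 0.301). In WT cells at 5 µM Tnrc6c (-2.33 ± 0.42) and Tnrc6a (-1.62 ± 0.21), scaffold proteins of microRNA silencing, fell, 2 of 19 by either adjustment (list median -0.46, camera adjusted p = 0.0701). The limit set by the ribosomal RNA control in untreated WT cells holds for these falls as well. With 5 µM in both lines Tnrc6a was higher in CDKO than in WT cells by 1.52 ± 0.21 (limma, adjusted p = 0.0176). Adjusted over the list alone, Ago3 was also higher there (2.26 ± 0.47), and Tnrc6a passed in the difference between the lines (1.62 ± 0.29).

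On the deposited scale, the 7 list calls that held with an estimated correlation were those of the cholesterol genes in CDKO cells at 5 µM against untreated cells and against 1 µM and in WT cells, of the NRF2 and aryl hydrocarbon receptor targets in those 2 CDKO comparisons, and of the muscle and adipocyte markers between the untreated lines. After centring or quantile normalization the cholesterol call at 5 µM against untreated held in CDKO cells (median 1.21 and 1.12, adjusted p = 0.0213 and 0.0211 with an estimated correlation). It was lost in WT cells (adjusted p = 0.0579 and 0.0716), where the medians were no smaller (1.33 and 1.40) and all 20 genes were positive. The other 5 were not tested that way. With a fixed correlation 73 of 208 list tests passed. In treated CDKO cells against the control groups the mitosis genes had a median of -0.91, with Ube2c (-0.91 ± 0.15) named after its value was seen, the 1 of 25 called by either adjustment (camera adjusted p = 2.49e-10, adjusted p = 0.408 with an estimated correlation). Their centred median was 1.57 and 1.57 in untreated WT arrays, which had a raised 18S control. It was 0.46, -0.73, -0.46 and -0.46 in the other control arrays and -0.72, 0.78, -1.01 and -0.90 in treated CDKO arrays. Lysosome and autophagy genes had a median of 0.12 in treated CDKO cells against the control groups, with Psap at 1.29 ± 0.13 and Mcoln1 at 1.03 ± 0.20, 2 of 23 by either adjustment (adjusted p = 0.299 with an estimated correlation). Psap and Mcoln1 were already higher in untreated CDKO than in untreated WT cells, by 1.27 ± 0.20 and 1.38 ± 0.31. Chondrocyte and bone markers had a median of -0.21 in treated CDKO cells against the control groups, with Ibsp (-1.96 ± 0.12) the 1 of 3 by either adjustment (adjusted p = 0.232 with an estimated correlation). Ibsp stood at 8.54 in untreated WT cells and at 2.70 to 2.75 in the 4 other groups.

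The remaining lists are given for 5 µM against untreated CDKO cells, with Slc7a11 (3.07 ± 0.23) the only gene among them that passed over all genes. It belongs to the 24 unfolded protein and integrated stress response genes, whose median was -0.29 and mean -0.03 (2 rose and 1 fell when adjusted over the list alone, camera adjusted p = 0.301). The p53 targets had a median of 0.01 (0 of 24 by either adjustment, camera adjusted p = 0.992). The DNA replication genes (-0.24, 27 measured), actin and myofibroblast genes (-0.17, 20 measured), imprinted genes (-0.18, 18 measured) and fibroblast markers (-0.32, 14 measured) were shifted by camera with 0 called by either adjustment, and adjusted p = 0.663, 0.450, 0.450 and 0.450 with an estimated correlation. The imprinted genes and fibroblast markers turned without CDKO 5 µM replicate 1 (0.20 and 0.10), and differed by -0.45 and -0.89 within the higher and 0.15 and 0.10 within the lower spike-in class. Macrophage and leukocyte markers (0.20, 15 measured), Hox genes (0.04, 24 measured), epithelial (-0.06, 5 measured), muscle (-0.08, 11 measured), neural and glial (0.19, 8 measured), adipocyte (0.09, 6 measured) and bone markers (0.14, 3 measured) were not shifted and had 0 called by either adjustment. For the epithelial markers the mean (0.31) and the median differed in sign. The macrophage and leukocyte markers differed by 0.47 within the higher and -0.16 within the lower spike-in class, and turned without CDKO 5 µM replicate 1. Sex-linked markers (-0.25, 4 measured) and endothelial markers (-0.32, 3 measured) were not shifted and had 0 called over all genes and 1 lower when adjusted over the list alone.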

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

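All tests of explanations in this part were chosen after the result was seen, except the random assignments, the choices of groups, and the tests of RNA quality (36 probe sets), of growth for the cholesterol genes and of normalization. The response to 5 µM differed between the lines by the test of the difference itself for 72 probe sets. Among named genes the difference (CDKO minus WT, log2) was 7.03 for Sftpc, 5.79 for Ibsp, 5.71 for Krt8, 4.48 for Myl1, 4.32 for Gprin3, 3.98 for Nrcam, 3.72 for Saa3, 3.31 for Cdh1, 3.19 for Abcc4, 3.16 for Myh3, -3.10 for Angptl7, -2.98 for Hal, -2.31 for Gjb2, -2.18 for C1ql3, -2.17 for Hoatz and -2.13 for Pdlim2. Among lists the median difference was -0.29 for p53 targets, 1.26 for mitosis, 1.06 for DNA replication, -1.80 for interferon-stimulated genes, -0.34 for cholesterol, -0.29 for hypoxia, 3.01 for epithelial, 2.37 for muscle, 1.78 for adipocyte and 1.12 for bone markers. These 10 lists passed by camera with a fixed correlation, and none did with an estimated one (adjusted p = 0.0868 to 0.505). The 18S control, which no comparison uses, stood at 10.2 in CDKO 1 µM replicate 2.

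For treated CDKO cells against the control groups, 2 of 100 random assignments of the arrays to groups, the real one included, called as many probe sets as the real 843. Chance can be excluded only against such assignments, most of which part the WT replicates (correlated at 0.997 and 0.998), and not for the grouping of the CDKO arrays or the choice of these groups. The highest other assignment, with 1 replicate pair intact, called 1917, which points to a structure of the samples: its group of 4 held CDKO untreated replicate 2, CDKO 1 µM replicate 1 and both 5 µM arrays, 3 of them in the lower spike-in class, and with that class as a block the real count was 259. Of the 10 choices of 2 of the 5 groups, 5 called at least as many, the real one included, and the highest other, both WT groups, called 2297. These 10 are too few for a share under 0.05.

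The CDKO replicates lay apart: the replicate differences of the untreated and 5 µM groups, each with 1 array per spike-in class, correlated at 0.431 across probe sets, which are not independent, so a hybridisation batch may account for part of their scatter, whereas the 1 µM pair, both in the lower class, correlated at only 0.976. An exchange of 5 µM labels with other CDKO arrays is argued against by the cholesterol list, but that list was singled out after it was called with these labels. In WT cells, which share no array with them, it also stood higher at 5 µM (0.80 and 0.81 against -0.64 and -0.59). Its array median stood higher by at least 1.04 in both CDKO 5 µM arrays than in the 4 other CDKO arrays. Among those 4 an exchange stays open, as CDKO 1 µM replicate 2, with no better CDKO partner than 0.980, fixes the worst pair of the best of 15 pairings; its nearest array was WT untreated replicate 1 (0.982), but Esr1 stood at 8.85 in it and at most at 4.57 in WT arrays. The mitosis genes differed between replicates more than 100% of random lists in the untreated and 1 µM groups but only more than 33.9% at 5 µM, so growth of the cultures may contribute in the former. Apart from growth, no biological explanation was tested.

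A set of 36 probe sets, among them those of Sftpc, Krt8 and Ibsp, was at 6 or above in untreated WT cells and below 4 elsewhere. RNA quality stays open: 5.56% of them were at 4 or above in CDKO 1 µM replicate 2, the 1 other array with a raised 18S control, but they were chosen as low in its group, and of 41 chosen without that array 17.1% were. Cells of another type stay open: 44.4% of muscle, 21.4% of epithelial and 9.09% of bone and cartilage markers were raised in untreated WT cells. However, 8 of 18, 9 of 14 and 8 of 11 had no signal there. Of those with signal, 8 of 10 muscle, 3 of 5 epithelial and 1 of 3 bone and cartilage markers were raised. Another line, with 73.3% of line-separating probe sets placing untreated with treated WT cells, also stays open, between the bounds set. An effect of OHT on these transcripts stays open and untested.

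The cholesterol genes were higher at 5 µM in both lines. Batch is argued against by the lower within-class median of 1.17. In CDKO cells growth is argued against by a median of 1.02 with the mitosis median as a covariate (adjusted p = 0.0256 with an estimated correlation). The covariate's slope came mostly from the untreated and 1 µM CDKO pairs, which also differed in spike-in class or 18S control. In WT cells, whose replicates did not differ in mitosis (1.57 and 1.57, -0.46 and -0.46), growth cannot be told apart from treatment. Centring and quantile normalization moved the median over all probe sets by only 0.054 and -0.020 in CDKO and -0.0051 and 0.051 in WT cells. They could not have lowered the list medians much, the lowest being 1.12, so normalization stays open. The WT call had adjusted p = 0.0579 after centring and 0.0716 after quantile normalization with an estimated correlation, at medians of 1.33 and 1.40. In WT cells the covariate lowered the median from 1.33 to 0.92 (adjusted p = 0.0455), and the genes called fell from 937 to 33, and from 20 to 2 in CDKO cells. A candidate explanation is an effect of the drug that does not need the conditional allele. This hypothesis came from the same data and was not itself tested, and in WT cells treatment went together with the 18S control.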

How the results depend on the processing

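The blocks for spike-in class and crossed replicates, the comparison without untreated WT cells and the list tests without each array were chosen after the data were seen. A trended robust prior, centring and a minimum change of 1 kept every count within 1.5 times. For the values that moved the cause was not tested, except that 1 probe set per gene and the filters change the number tested, and that fits without the CDKO or the WT arrays pool another spread. Without a filter the counts were 46 for CDKO at 5 µM and 194 for the difference between lines, which was 32 with a filter at 6. Quantile normalization gave 16 for 5 µM against 1 µM. With 1 probe set per gene the counts were 184 for treated CDKO cells against controls, 21 for 5 µM against 1 µM, 937 for WT at 5 µM, 39 for the difference between lines, 422 between untreated lines and 156 between treated lines. Array weights gave 104, 2 for CDKO at 5 µM, 2 for 5 µM against 1 µM and 12458 for WT. The replicate block gave 538, 3, 3, 1190, 35 for the difference and 197 between treated lines. The compared groups alone gave, by limma, 0 for CDKO at 5 µM (993 at an unadjusted p under 0.05), 0 for 5 µM against 1 µM (996), 11308 for WT, 212 for the difference, 489 between untreated and 2 between treated lines. For treated CDKO cells against controls, 2 groups of 4 and 6 arrays gave 1, with a line term 0 by limma (427 at an unadjusted p under 0.05), and leaving out untreated WT cells 15. The spike-in class block gave 259, 2988 for WT, 2206 between untreated and 944 between treated lines. For 1 µM 0 passed by limma in every alternative that kept all arrays (156 to 1228 at an unadjusted p under 0.05).

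Leaving out 1 array leaves a group with 1, which is assumed to vary like the others. The counts ranged from 142 to 1455 for treated CDKO cells against controls, 0 to 121 for CDKO at 5 µM, 0 to 467 at 1 µM, 3 to 1901 for 5 µM against 1 µM, 64 to 4503 for WT, 9 to 212 for the difference, 243 to 3214 between untreated and 29 to 594 between treated lines, and 68 to 85 for lists. An estimated correlation gave 7 list shifts and fry 47, against 73. The cholesterol list was called in all 16 list alternatives, which include no other scaling, in CDKO at 5 µM (1.00 to 1.28), against 1 µM (1.03 to 1.31) and in WT cells (1.29 to 1.38), and the NRF2 list in the first 2 of these (0.58 to 1.11 and 0.51 to 1.80).

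Of the named-gene results over all alternatives 1559 kept direction and side, 519 lost the call, 8 gained it and 6 reversed. With a line term Zfp991 (-0.037), Serpina3n (-0.011), Ccl6 (0.38), Hddc3 (0.094) and Sftpc (0.13) reversed in treated CDKO cells against controls, and Sftpc also without untreated WT cells (0.13). Of the list results 3032 kept both, 174 lost the call, 101 gained it and 13 reversed. Hypoxia genes reversed in treated CDKO cells against controls with the class block (-0.15). Without CDKO untreated replicate 1 p53 targets reversed at 5 µM (-0.18) and 1 µM (-0.14). Without CDKO 1 µM replicate 2 mitosis reversed at 1 µM (-0.52, and up to 0.89 without another array) and interferon genes in 5 µM against 1 µM (-0.39, and up to 0.35). Without CDKO 5 µM replicate 1 extracellular matrix reversed against controls (0.30, lowest otherwise -0.28), at 5 µM (0.087, lowest -1.47), in the difference (0.77, lowest -0.62) and between treated lines (0.66, lowest -0.71). Imprinted genes (0.20, lowest -0.53) and fibroblast markers (0.10, lowest -0.79) reversed at 5 µM, and macrophage markers at 5 µM (-0.64, highest 1.09) and in the difference (-0.51, highest 1.00). With the mean over a gene's probe sets the sex-linked list had too few genes left and gave no value. The test of microRNA sites was not run. Signal near the background limits what can be seen: at most 43.2% of probe sets reached 4 in an array.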

Other observations

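Markers of both sexes were present in every group. Xist, which is transcribed from the inactive X chromosome, had group means of 8.97 to 10.51, and Eif2s3y, on the Y chromosome, 7.96 to 8.72 (log2, n = 2 each).

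The test of this part was chosen after the result was seen. In every CDKO array 1 Esr1 probe set was high, while the highest CDKO group mean of the other Esr1 probe sets was 3.65. Those probe sets had group means under 4 in WT cells as well, so their low signal does not decide whether a transgene carries part of the estrogen receptor. The labels name no such transgene, and a transcript variant was not tested.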
